A study of Mus musculus with 10 samples.

How the data were processed

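Gene expression was measured in the brains of 5 male Cin85-/- mice, 15 weeks old, on two-colour arrays. Cin85 is the product of Sh3kbp1, an adaptor protein with SH3 domains. Each mouse was hybridised on 2 arrays against a single pool of wildtype brain RNA, once with its own RNA labelled with Cy5 and once with Cy3, which makes 10 arrays. The series design and the listed animals give 5 wildtype mice in the pool, while the labelling protocol gives 6. Per the labels' protocols, total RNA was extracted with a column kit, checked on a gel, reverse transcribed and labelled indirectly with the dyes. The scanner, the background correction and the normalization are not given in the sources used here. The sample titles and the pool name brain as the tissue, and the source name of the mutant channel carries an abbreviation, Kdn, that the labels do not explain.

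The deposited values are log2 ratios of the authors, with 20355 probes on each of the 10 arrays. The log2 scale fits the range and the symmetry of the values, and the medians of the arrays lay between -0.008 and 0.027, so each array had been centred or nearly so. Which channel is the numerator, and whether the arrays with the mutant in Cy3 had already been turned to the direction of the others, is not given in the sources used here. No channel intensity was analysed here, so the signal over background is unknown, and the number of arrays limits the precision. Each array held a single extreme value, between 16.437 and 17.64 in size, at between 65 and 264 probes, while no other ratio exceeded 9.202. These 1024 values are called capped ratios below. They were kept in the main analysis and set to missing in an alternative.

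Probe names came from the platform annotation, which can be old and in which 14030 probes carried 1 gene symbol, 5 carried several and 6320 carried none, for 9930 different genes. Of the probes with a gene, 13994 had an Entrez identifier found in the mouse RefSeq table of GRCm38.p6, and 0 symbols changed through it. Probes with several symbols were not named. No coordinates are given, because no genome build is named for the arrays.

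The columns were centred on their median, the 2 arrays of a mouse were averaged as deposited (the pair mean), and the 5 pair means were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A probe needed a value on both arrays of at least 4 mice. The mouse was the replicate, and its 2 arrays counted as 1. The pool is a single control sample, so the test leaves out the spread between wildtype mice. A size limit of 1.5-fold was also applied. The dye term of a probe is the ratio on the array with the mutant in Cy5 minus that on the array with the mutant in Cy3, divided by 2, and it was tested in the same way. If the deposited columns all run Cy5 over Cy3, the dye term is the difference from the pool and the pair mean is the dye bias. This is called the other reading of the swap. Whether the arrays of a mouse deviate together was tested with an exact permutation test over the 120 pairings of mice between the 2 dye orientations, after the probe means of each orientation were removed.

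Gene lists were tested over 7371 genes, with the probes of a gene averaged, by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, and adjusted over the 30 lists. Camera compares a list with the other genes, and fry asks whether its members move, on balance, in a single direction. The members of each list were also counted with p adjusted over the list alone. The list of genes near Sh3kbp1 held 28 names, all within 50 protein-coding genes of it in the RefSeq gene order. The lists, the tests and the rule for named genes were fixed before the data were examined. By this rule every probe of Sh3kbp1 was named first. Of probes past the threshold with the same sign in all 5 mice and in both dye orientations, the largest changes were to be named. Since fewer than 10 passed, the 10 named probes with the smallest p were given as values and not as changes. From each list, up to 2 members with the smallest p were selected as values, because no member passed over its list alone. Not all of those selected are printed below.

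The scripts were tested on simulated data with the real spread of the 16939 probes, of which 200 were changed in each of 5 runs. The test recovered 0% of the probes changed by 1.5-fold, 47.3% at 2-fold, 75.2% at 3-fold and 83.1% at 4-fold. A shift of -0.07 given to 53 ribosomal protein genes was called in 4 of 5 runs by camera with the preset correlation, in 2 by fry and in 0 with an estimated correlation. At a shift of -0.15 it was called in 5, 5 and 4 runs.

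Alternatives planned in advance were no centring, scaling between arrays, all 10 arrays in the fit with the mouse as a random block with and without a dye covariate, the other reading of the swap, each dye orientation alone, a stricter and no filter on missing values, robust moderation, a one-sample test without variance moderation, the gene as the unit, a threshold of 0.10, the most complete probe of each gene, and each mouse left out in turn. Chosen after seeing the data were capped ratios set to missing, rank correlation in the permutation test, array quality weights, mouse 3 represented by its Cy5 array alone, the other reading applied to the gene lists, list members without each mouse on the probes of the main analysis, and the dye term from all 10 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.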

Results

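Brain RNA of 5 male Cin85-/- mice, 15 weeks old, was compared with a pool of wildtype brain RNA on 10 two-colour arrays, 2 per mouse with the dyes swapped. The comparison asks which transcripts differ in the brain without Cin85, an adaptor that binds Cbl ubiquitin ligases and endophilins and takes part in the uptake of receptors from the cell surface. The arrays held between 16816 and 19424 values each, and 16939 probes had a value on both arrays of at least 4 mice.

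Sh3kbp1, the gene that encodes Cin85, gave a mean log2 ratio of 0.0082 ± 0.139 (SD, n = 5 mice) on probe 8640, with a 95% interval from -0.227 to 0.243 and an adjusted p of 0.989 by limma. The pair means of the 5 mice on this probe were 0.0175, 0.006, -0.162, 0.222 and -0.042. The targeted gene was therefore not lower on this probe by more than the spread between mice. The part of the transcript that the probe covers is not given in the sources used here. A probe outside the deleted part need not read lower, so this value does not settle whether the gene was lost. Gene names come from the platform annotation. Over 2270 genes, distant probes of a gene did not share the spread over arrays (rho 0.0349). A single name was therefore not checked by a second probe, and a wrong name gives the value of another gene. The pair mean was not shared either (rho 0.0067), but it was hardly shared between mice (median rho 0.0144), so this checks no name. The median spread was 0.312 for ribosomal protein probes and 0.317 for oxidative phosphorylation probes. All 2000 random draws of as many named probes lay above these (lowest 0.372 and 0.388). This comparison, chosen after the values were seen, argues against names that are wrong throughout. The second Sh3kbp1 probe, 4508, had values on only 4 of 10 arrays and was not tested. They were 2.71, 3.19 and a capped ratio of 17.64 with the mutant in Cy5, and -2.35 with it in Cy3, so their signs followed the dye orientation. Only mouse 4 had both arrays, with a pair mean of 0.41 and a dye term of 2.78. These values cannot separate dye bias from a difference under the other reading of the swap. Signs are those of the deposited scale, and none of them settles which sample was higher. The numerator of the ratios is not stated, and Sh3kbp1 probe 8640 did not point either way. Same-mouse arrays had a mean residual correlation across probes of -0.0196. The exact permutation p was 0.81 for a value as high and 0.20 for a value as low, each one-sided, where 0.0083 is the smallest this test can give. Probes are not independent replicates in this correlation. Under the other reading of the swap, in which the Cy3 columns change sign, Sh3kbp1 probe 8640 gave 0.12 ± 0.089 (SD, n = 5), with an adjusted p of 0.442 by limma.

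With the ratios taken as deposited, no probe differed between Cin85-/- brain and the wildtype pool at an adjusted p under 0.05 by limma, with 0 positive and 0 negative among 16939, and the smallest adjusted p was 0.911. At an unadjusted p under 0.05 there were 632 probes, 328 positive and 304 negative, against 847 expected by chance. With the gene as the unit, 0 of 8711 genes passed and 307 had an unadjusted p under 0.05. A one-sample test without variance moderation also called 0 probes, with 713 at an unadjusted p under 0.05. Among 13572 probes measured in all 5 mice, 952 had the same sign in each, which is 7.01%, where independent random signs give 6.25% and the pool shared by the 5 mice can give more without any change. The 95% interval of the pair mean lay within 1.5-fold for 10282 probes (60.7%), within 2-fold for 14538 (85.8%) and within 4-fold for 16590 (97.9%). Under the other reading of the swap the intervals lay within 1.5-fold for 6594 probes (38.9%), within 2-fold for 13466 (79.5%) and within 4-fold for 16523 (97.54%). Limma on the mouse values called 0 probes under that reading too, but the smallest adjusted p was 0.0988, 4679 probes had an unadjusted p under 0.05, and 4136 of 13572 (30.5%) had the same sign in all 5 mice. There 257 probes passed after scaling between arrays. With all 10 arrays in the fit, a dye covariate and the mouse as a random block, 2054 passed, but the within-mouse correlation was estimated at -0.0196, so the 10 arrays of 5 mice counted as about 10 replicates and this count overstates what 5 mice support. On simulated data with 200 changed probes and each probe's observed spread taken as its true one, the test recovered 0% of 1.5-fold changes and 47.3% of 2-fold changes. In that setting 1.5-fold changes in single genes were not detected, and other settings were not simulated.

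The named probe with the smallest p belonged to Plcd4, a phospholipase C of the delta class, with a mean log2 ratio of 1.37 ± 0.14 (SD, n = 4). Kitl, the ligand of the receptor tyrosine kinase Kit, gave 1.21 ± 0.32 (SD, n = 5). The value of Cdk19, a kinase of the Mediator complex, was 1.12 ± 0.23 (SD, n = 4), and that of Pcif1, which methylates the mRNA cap-adjacent adenosine, was 1.27 ± 0.62 (SD, n = 5). Cep83, a protein of the distal appendages of centrioles, had 0.96 ± 0.42 (SD, n = 5), and Hipk1, a nuclear protein kinase, had 0.63 ± 0.068 (SD, n = 4). Negative means were those of Dlgap4, a scaffold protein of the postsynaptic density, at -0.92 ± 0.30 (SD, n = 5), and Adamtsl2, a secreted matrix protein, at -0.80 ± 0.19 (SD, n = 5). Bcl2l11, the proapoptotic protein Bim, gave -0.73 ± 0.19 (SD, n = 4), and Cndp2, a cytosolic dipeptidase, gave -0.68 ± 0.27 (SD, n = 5). All 10 had an adjusted p of 0.911 by limma, so these are values and not changes. They are the smallest p-values among many probes, and such values tend to overstate the size. Means of the array orientations had opposite signs for Cndp2, Hipk1 and Bcl2l11, and with the mutant in Cy3 alone the means were 0.68 for Plcd4, 0.585 for Kitl, 0.48 for Cdk19 and -0.46 for Adamtsl2. For 4 of these probes the mean leaves out an array whose swap partner had no value, which for Plcd4 was -3.585 in mouse 3. With all 10 arrays in the fit, which takes these in, Plcd4 had 0.85 and Bcl2l11 -0.47 with a dye covariate, and Hipk1 had 0.40 without it.

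Kitl and Adamtsl2 had no second probe, and further probes of the other 8 genes gave means nearer to 0. The second Plcd4 probe gave 0.14 ± 0.43 (SD, n = 5), and the second Dlgap4 probe gave 0.073 ± 0.83 (SD, n = 5). For Cep83 the second probe had 0.10 ± 0.40 (SD, n = 5), and for Cndp2 it had -0.13 ± 0.43 (SD, n = 5). The 3 further probes of Cdk19 had means of 0.069, -0.30 and -0.10, those of Pcif1 had -0.08, 0.036 and -0.086, the 2 of Hipk1 had 0.083 and -0.056, and the 2 of Bcl2l11 had 0.042 and -0.05. Under the other reading of the swap the means were -0.38 for Plcd4, 0.62 for Kitl, -0.34 for Adamtsl2, 0.29 for Cdk19, -0.13 for Dlgap4, -0.058 for Cep83, -0.30 for Pcif1, 0.75 for Cndp2, 0.74 for Hipk1 and 1.62 for Bcl2l11.

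**Figure D1:**
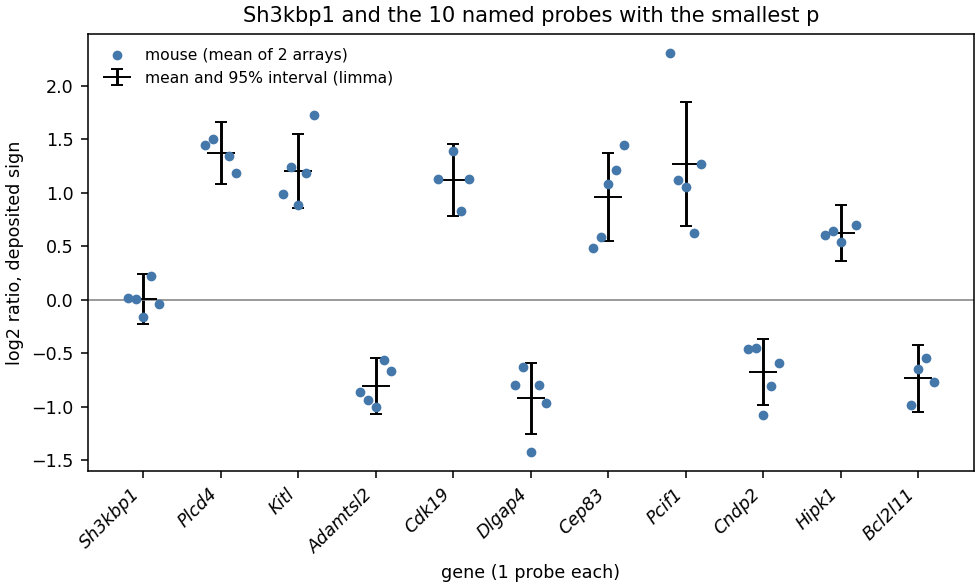
Log2 ratios on the deposited scale for Sh3kbp1 (probe 8640) and the 10 named probes with the smallest p, with 1 point per mouse (mean of 2 arrays) and the mean with its 95% interval from limma. Sh3kbp1 lies at 0.0082 with an interval across 0, and the other means run from -0.92 (Dlgap4) to 1.37 (Plcd4), none past the adjusted threshold.

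Genes of the cytosolic ribosome had negative ratios more often than positive. Of 56 measured ribosomal protein genes, 46 were negative and 10 positive, with a median of -0.074, and the list median was negative in each of the 5 mice, from -0.141 to -0.0507. The list was called by camera with the preset correlation (median -0.071 over 53 genes, adjusted p = 0.00687) and by fry (adjusted p = 0.00027). With an estimated correlation the camera adjusted p was 0.315, so the call is lost there. That correlation was -0.0173, below the preset 0.01, so sharing between members was not the reason. In simulation this setting called a shift of -0.07 in 0 of 5 runs, so its loss here decides nothing. The call also ended in camera without mouse 1 (adjusted p = 0.157) or without mouse 2 (adjusted p = 0.0735), and in fry without mouse 3 (adjusted p = 0.0647), mouse 4 (0.0707) or mouse 5 (0.0735). The list median itself was between -0.082 and -0.073 without each mouse in turn, against -0.071 with all 5. The filter was applied anew each time, so the genes could differ. Under the other reading of the swap the median was -0.021, with an adjusted p of 0.917 by camera. No member passed by limma, adjusted over the list alone or over all genes. Rpl30 gave -0.21 ± 0.07 (SD, n = 5) and Rps18, against the list, 0.33 ± 0.23 (SD, n = 5).

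Genes of oxidative phosphorylation were also mostly negative, with 42 of 62 measured genes below 0 and a median of -0.064, but the list missed the threshold (camera adjusted p = 0.0569, fry adjusted p = 0.162). Atp5o, a subunit of the ATP synthase, gave -0.23 ± 0.15 (SD, n = 5), and Cox7c, a subunit of cytochrome c oxidase, gave -0.19 ± 0.12 (SD, n = 5). Of 15 choroid plexus and ependyma genes, 11 were negative, with a median of -0.072, a camera adjusted p of 0.0569 and a fry adjusted p of 0.196. The median over the genes of the set test was -0.08, and without mouse 1, on genes filtered anew, it was -0.036, with a camera adjusted p of 0.379. Ttr, which encodes transthyretin, the main secreted protein of the choroid plexus, had -0.35 ± 0.21 (SD, n = 5), and Sostdc1, a secreted inhibitor of Wnt and BMP signalling, had -0.32 ± 0.14 (SD, n = 5). Both lists were called when each gene was represented by its most complete probe, with adjusted p of 0.0175 and 0.0364, and neither was called with an estimated correlation.

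The kidney list was tested because of the abbreviation in the source name. Of 19 measured genes, 12 were positive and 7 negative, with a median of 0.145, and camera with the preset correlation called the list as positive (adjusted p = 0.046). With an estimated correlation the adjusted p = 0.368, and fry gave an adjusted p of 0.22. The median over the 16 genes of the set test was 0.161, fell to 0.027 without mouse 3 and was -0.18 under the other reading of the swap. The genes without mouse 3 were not the same 16. Umod (-0.37), Aqp2 (-0.092) and Odc1 (-0.042) had no value in mouse 3 and entered only there, so the fall is not due to that mouse's values alone. The mouse medians were 0.272 in mouse 3, 0.114 in mouse 2 and 0.005, 0.0035 and 0.0025 in mice 1, 4 and 5. The call ended without mouse 1, 2, 3 or 5, with adjusted p of 0.128, 0.188, 0.424 and 0.0971, as it did without centring (0.052), with capped ratios missing (0.052) and with the most complete probe of each gene (0.12). Napsa, an aspartic protease, gave 0.89 ± 0.57 (SD, n = 5) over 2 probes, and 0.21 on its most complete probe. Slc22a12, the urate transporter of the proximal tubule, gave 0.22 ± 0.30 (SD, n = 5).

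The other 26 lists were not called, with camera adjusted p from 0.186 to 0.912 and medians from -0.095 to 0.057. No member of any of the 30 lists, out of 594 measured genes, passed by limma adjusted over the list alone. Among the partners of CIN85 and its adaptor family, 13 genes were positive and 12 negative. Cblb, a ubiquitin ligase that CIN85 binds, had 0.31 ± 0.27 (SD, n = 5), and Sh3gl2, which encodes endophilin A1, had 0.37 ± 0.43 (SD, n = 5). Clathrin endocytosis and early endosome genes divided into 18 positive and 17 negative, with Vps28 at 0.23 ± 0.19 (SD, n = 5) and Amph at -0.28 ± 0.16 (SD, n = 4). Receptor tyrosine kinase signalling had 9 positive and 13 negative members, among them Egfr at 0.18 ± 0.15 (SD, n = 5) and Map2k2 at 0.18 ± 0.13 (SD, n = 5). Of the X-linked genes near Sh3kbp1, 3 were positive and 5 negative, with Klhl34 at -0.27 ± 0.27 and Sms at 0.17 ± 0.17 (SD, n = 5 each).

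Neuronal lists were not called either. In the dopamine system 7 genes were positive and 12 negative, with Pts, an enzyme of tetrahydrobiopterin synthesis, at -0.46 ± 0.32 (SD, n = 5). Striatal neuron genes were 9 and 9, with Rgs9 at 0.24 ± 0.13 (SD, n = 5) and Adcy5 at -0.21 ± 0.077 (SD, n = 5). Glutamate receptors and the postsynaptic density had 5 positive and 13 negative genes, with Dlg3 at -0.29 ± 0.39 and Grin2c at -0.15 ± 0.25 (SD, n = 5 each). Presynaptic vesicle release had 9 and 12, with Syngr1 at 0.33 ± 0.34 (SD, n = 4) and Sncb at 0.21 ± 0.32 (SD, n = 5). For GABAergic neuron genes the counts were 3 and 9, with a median of -0.095 and a camera adjusted p of 0.186, and Gphn had -0.19 ± 0.17 (SD, n = 5). Immediate early genes were 8 and 11, with Nr4a3 at -0.81 ± 0.87 (SD, n = 4) and Junb at -0.42 ± 0.56 (SD, n = 5). Circadian clock genes were 4 and 8, with Tef at -0.97 ± 1.07 (SD, n = 4) and Per3 at 0.38 ± 0.37 (SD, n = 4). Hypothalamic and pituitary hormones were 7 and 7, with Cga at 0.56 ± 0.55 and Tshb at -0.47 ± 0.49 (SD, n = 5 each), where mouse 3 alone had 1.52 for Cga.

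Regional lists gave 8 positive and 6 negative genes for hippocampus and cortex layers, 6 and 8 for cerebellum, 2 and 5 for thalamus, and 8 and 6 for olfactory bulb and neurogenesis. Grik4 had 0.51 ± 0.83 (SD, n = 4), and Prox1, a marker of the dentate gyrus, had -0.17 ± 0.33 (SD, n = 5). Zic1 had -0.20 ± 0.23 (SD, n = 5) and Reln had -0.25 ± 0.34 (SD, n = 5). Nrep had -0.17 ± 0.26 (SD, n = 5) and Tubb2b had 0.16 ± 0.30 (SD, n = 5). Glial and vascular markers went both ways. Oligodendrocyte and myelin genes were 8 positive and 7 negative, with Cnp, an enzyme of myelin, at 0.27 ± 0.068 (SD, n = 5) and positive in all 5 mice. Septin4 of the same list had -0.33 ± 0.39 (SD, n = 5). Astrocyte genes were 9 and 10, with Aqp4 at -0.20 ± 0.14 and Glul at 0.16 ± 0.08 (SD, n = 5 each). Microglia and macrophage genes were 5 and 9, with C1qa at -0.17 ± 0.088 and Ctss at -0.15 ± 0.08 (SD, n = 5 each). Endothelium, pericyte and meninges had 11 and 8, with Col3a1 at 0.77 ± 0.64 (SD, n = 5), and red blood cells had 3 and 3.

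Proteasome and ubiquitin genes had 8 positive and 20 negative members, a median of -0.063 and a camera adjusted p of 0.186, with Ube2d3 at -0.90 ± 0.41 (SD, n = 4). Heat shock and the unfolded protein response had 14 and 12, with Hspa1a at -0.43 ± 0.43 (SD, n = 4). Interferon and antigen presentation had 9 and 9, with Mx2 at 0.24 ± 0.15 (SD, n = 5). Actin cytoskeleton genes were 18 and 11, with Vasp at -0.57 ± 0.39 (SD, n = 4) and Vcl at 0.36 ± 0.44 (SD, n = 5), of which mouse 3 had 1.13. Tubulin, neurofilament and axon transport genes were 14 and 18, with Nefh at 0.49 ± 0.36 (SD, n = 4) and Tubb6 at 0.49 ± 0.51 (SD, n = 5). Under the other reading of the swap, 0 of the 30 lists were called by camera or fry, and 30 of the 58 named list values had the opposite sign. Leaving out 1 mouse moved 29 of the 58 by over 1.5 times and 11 by over 2 times, among them Grin2c to -0.053, Sncb to 0.088, Prox1 to -0.065 and Vcl to 0.17 without mouse 3, Slc22a12 to 0.10 without mouse 5 and Tubb2b to 0.075 without mouse 2. Grik4 also moved by over 2 times, to 0.12 without mouse 4. Without mouse 1, Tef moved to -0.57, Hspa1a to -0.26, Septin4 to -0.18 and Nrep to -0.089. Without mouse 2, Sh3gl2 moved to 0.20. Without mouse 3, Cga moved to 0.32, Zic1 to -0.11, Nefh to 0.33 and Sms to 0.10, and without mouse 4, Per3 moved to 0.24. Without mouse 5, Dlg3 moved to -0.17, Syngr1 to 0.17, Junb to -0.26, Vasp to -0.38 and Reln to -0.16.

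**Figure D2:**
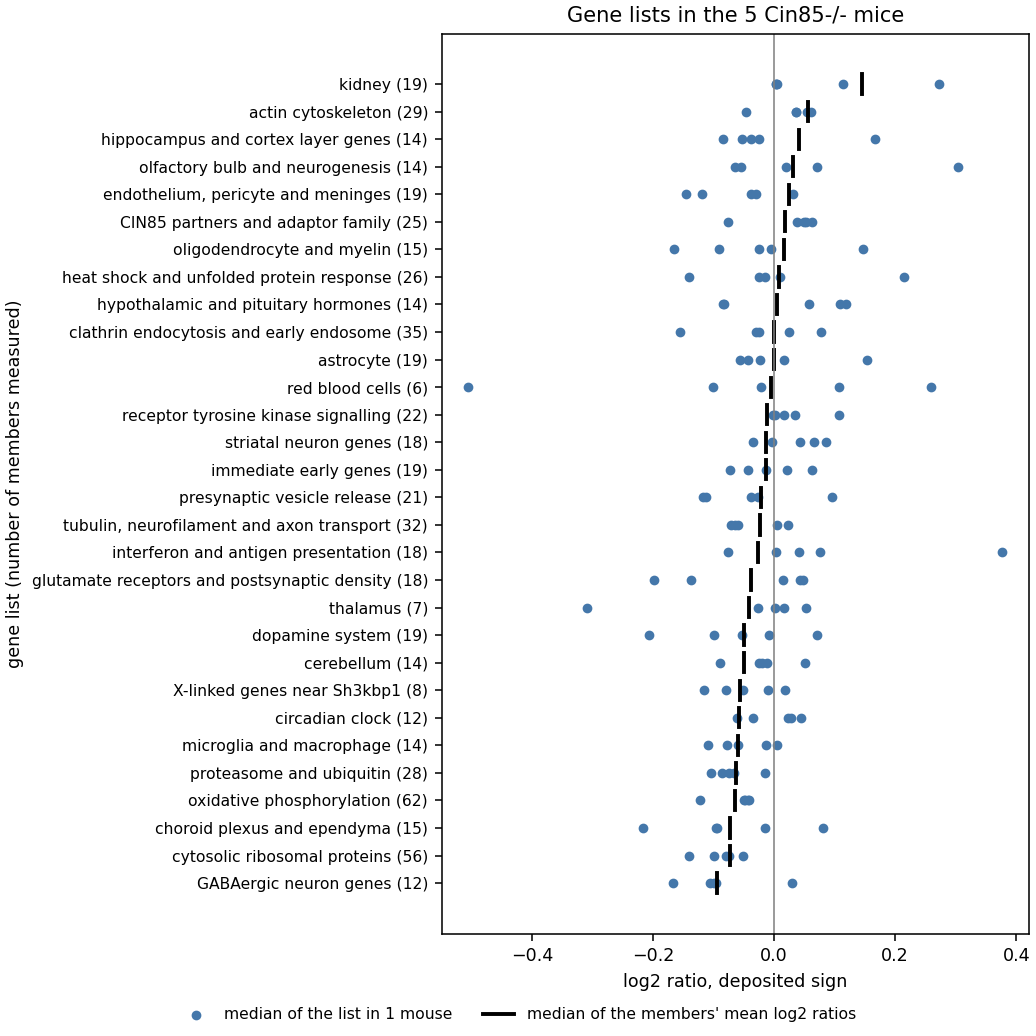
Median log2 ratio on the deposited scale of the 30 gene lists (vertical axis, with the number of members measured), with 1 point per mouse and a bar for the median of the members' means. The ribosomal protein points lie between -0.141 and -0.0507, and the kidney point of mouse 3 lies at 0.272.

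A signal shared by most arrays followed the dye orientation. Arrays with the mutant in the same dye had a median Spearman correlation across probes of 0.276, and dye-swap arrays of a mouse had -0.33, with probes not being independent replicates. The dye term, which is the difference from the pool under the other reading of the swap, had the same sign in all 5 mice for 30.5% of probes, a share that dye bias or a deviation of the shared pool also gives. Limma called 776 probes for it at an adjusted p under 0.10 and 0 under 0.05, with 257 under 0.05 after scaling. Correlations between mice were 0.105 to 0.599 for the dye term and -0.125 to 0.0893 for the pair mean. The array of mouse 3 with the mutant in Cy3 stood apart, with a median correlation of -0.048 with its own orientation.

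**Figure D3:**
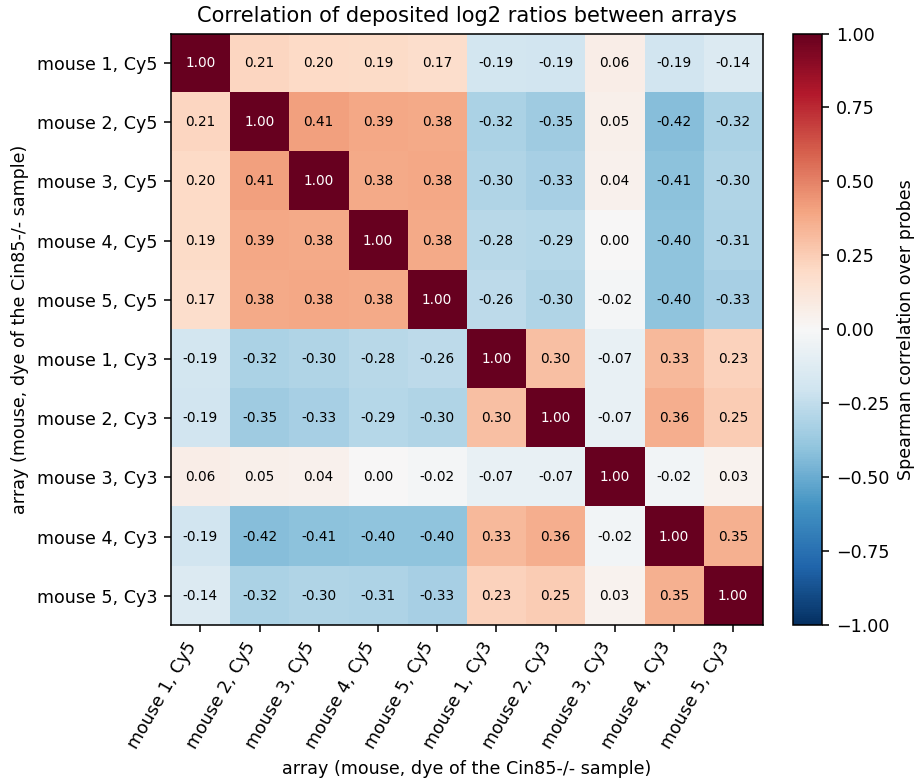
Spearman correlation across probes between the 10 arrays, ordered by the dye of the Cin85-/- sample (colour and number in each cell, from -1 to 1). Arrays of the same orientation correlate above 0 and those of opposite orientation below 0, except for the Cy3 array of mouse 3, whose median correlation with its own orientation is -0.048.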

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

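Of 104 groups of values searched for a value far from the rest, 10 held such a value, where chance alone gives about 5%. Among the tests below, those on the signs of the capped ratios, on kidney tissue and on the kidney list on single arrays were chosen only after the result was seen, and so were the allowance for 30 lists beside the matched percentiles and the comparison of spread between probes of a gene. Setting the dye trend test aside for the small size of its correction was also decided after the values were seen. The reading of the dye term by probe order was not among the planned tests.

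The array of mouse 3 with the mutant in Cy3 had 3539 missing values against 1582 on the next array, and 264 capped ratios against 117. Its median correlation across probes with arrays of its orientation was -0.0481, against 0.197 for the next lowest. Mouse 3 also stood apart for Cga, at 1.52 against 0.421 in the nearest mouse, and for Vcl, at 1.13 against 0.292. The CIN85 partner list had a median of -0.0758 in mouse 5, below the other mice. The hippocampus and cortex list had 0.167 in mouse 2, above the others. Thalamus genes had -0.309 in mouse 5. Oxidative phosphorylation had -0.123 in mouse 4. The actin cytoskeleton list had -0.0473 in mouse 5.

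The arrays of opposite dye orientation ran against each other across probes, and in 10 of 10 arrays the capped ratios all had the sign of the orientation, positive with the mutant in Cy5 and negative with the mutant in Cy3. That is consistent with ratios of fixed channels that were later turned to a common direction, so that the shared signal may be dye bias. A cap set only where the pool's channel read 0 would give these signs without any turning, so this is not decisive. A difference from the pool in columns left as Cy5 over Cy3 was tested by the dye term of distant probes of the same gene. Their correlation minus that of adjacent probes of different genes was -0.3204, below the planned bound of 0. But distant probes of a gene did not share their spread over arrays either (rho 0.0349, within the shuffled range up to 0.0611), so the planned bound was wrong. Adjacent probes of different genes shared the dye term (rho 0.32) but hardly the pair mean (rho 0.0311), and at a distance of 10 the dye term had rho 0.0141. A difference from the pool gives no reason to follow probe numbers, unless their order follows gene function, which was not tested. This argues against such a difference as the source of the whole dye term, and a smaller difference within it stays open.

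The ribosomal protein list lay below 0. The list median was at percentile 0.02 of 10000 lists matched on spread, a share of 0.012 after allowing for both sides and 30 lists, which argues against a bias set by the spread of a probe. Brightness could not be matched, since no channel intensity was analysed, so a bias set by brightness stays open. By the same matching, the oxidative phosphorylation list was at percentile 0.11, a share of 0.066. Removing the trend with the dye term took the median from -0.0706 to -0.07394, but the trend was near 0 (rho -0.044) and its removal moved a gene by a median of 0.0115, so the planned bound, set by the standard error of 0.0175, tests nothing and leftover dye bias stays open. Of the 16 sign patterns of the 5 mice, 1, the real one, gave a mean shift as large (0.0584, highest other 0.0444), and 16 patterns are too few for a share under 0.05. A deviation of the wildtype pool stays open and could account for it, since the design holds 0 other wildtype libraries, and an effect of Cin85 loss stays open as well.

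The kidney list lay above 0. Kidney tissue in place of brain was taken to need a median above 1, and the observed 0.145 argues against it, although 3 of the 46 listed genes are also in other lists and the ratios give no expression level. Noise in probes of genes that brain hardly uses was to be excluded by a median above the central 95% of matched lists, and the median was at percentile 99.8. That bound, set in advance, did not allow for the 30 lists searched, and the share becomes 0.12 with them, so noise stays open. On the Cy3 array of mouse 3 the kidney median was 0.503, above the range of the other 4 Cy3 arrays (-0.12 to 0.16). It covered 16 genes against 19 on every other array, since Umod, Aqp2 and Odc1 had no value there. Its Cy5 array, at -0.0615, lay below the range of the others (0.006 to 0.196). In ratios as deposited, a difference of that mouse would raise both arrays, and only the Cy3 array was high. Each value rests on 1 array, so neither a source in the Cy3 array alone nor a difference of that mouse is decided.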

How the results depend on the processing

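Alternatives with capped ratios set to missing, array weights, mouse 3 by its Cy5 array alone, rank correlation, the other reading for the gene lists, list members without each mouse on the probes of the main analysis and the dye term from all 10 arrays were chosen after seeing the data. The count of probes that differ was 0 under each of the 21 alternatives run for it, with and without the 1.5-fold limit. The other reading of the swap was 1 of these and was run there only on the values of the 5 mice. The probes at an unadjusted p under 0.05 numbered from 307 (genes as the unit) to 5055 (mutant in Cy5 alone), and the smallest adjusted p ran from 0.0749 to 0.942. The dye term gave 257 probes after scaling between arrays and 2054 with all 10 arrays in the fit, against 0 in the main analysis and 0 without each mouse in turn. The fit on all 10 arrays had a within-mouse correlation of -0.0196 with the dye covariate, and so counted the 10 arrays as about 10 replicates where there are 5 mice. The cause of the 257 was not tested. Camera with the preset correlation called 2 lists. That became 3 with the most complete probe of each gene (choroid plexus, ribosomal proteins and oxidative phosphorylation, and not kidney), 1 without centring, 1 with capped ratios missing, 0 with an estimated correlation and 0 under the other reading, fry called 1 (2 with the most complete probe), and leaving out each mouse gave between 0 (mouse 1 or mouse 2) and 2, again with the cause not tested. The kidney median turned to -0.18 under the other reading, which is by construction another quantity. Of 176 values of the 10 named probes under alternatives that keep the reading, 173 kept their direction, though not always their size. The exceptions were Cndp2 (0.079) and Bcl2l11 (0.89) with the mutant in Cy5 alone, and Hipk1 (-0.50) with it in Cy3 alone. Of 522 such values of list members, 519 kept theirs. The exceptions were Slc4a1, at -0.21 without mouse 4, and Amph, at 0.091 without mouse 1 and 0.032 without mouse 3. The Amph values come from a second probe that passed the filter with fewer mice, and the probe of the main analysis alone had -0.33 without mouse 1 and no value in mouse 3. On the probes of the main analysis 277 of 278 values without a mouse kept their direction. The named probes and list members were picked for small p in these same data. The 10 named probes also had the same sign in every mouse measured. Most alternatives use the same arrays, so kept directions were largely given by this choice and lend no support. The orientation test gave -0.0131 without capped ratios and -0.0172 by rank. Signal over background is unknown, so its effect could not be assessed.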

Other observations

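The median spread of a list over arrays within an orientation ran from 0.294 for astrocyte probes to 0.631 for kidney probes among the 30 lists, against 0.506 over all probes. It was 0.312 for cytosolic ribosomal proteins, 0.317 for oxidative phosphorylation, 0.35 for GABAergic neuron genes, 0.372 for red blood cells and 0.562 for circadian clock. Against 2000 random draws of as many named probes, a comparison chosen after the values were seen, 7 of the 30 lists lay below the central 95% and 0 above it, and 4 lay below all draws (astrocyte, oxidative phosphorylation, ribosomal proteins, and tubulin, neurofilament and axon transport). With draws from the same block of 1000 probe numbers these counts were 6, 0 and 4. Spread thus followed the gene names for the lists below the central 95%, while the other lists lay within it.

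Probes of the same gene, lying over 100 probe numbers apart, did not share their measurements. Over 2270 genes the Spearman correlation across genes was 0.0067 for the pair mean (95% bootstrap interval -0.035 to 0.0479), 4.42e-05 for the dye term, 0.0349 for the spread over arrays and 0.0146 for the number of missing values, each within the range of 200 shuffles. The pair mean was hardly shared between mice (median rho 0.0144), so its correlation would be near 0 with right names too. Whether dye bias is shared by probes of a gene was not tested, so only spread and missing values bear on the names. Adjacent probes of different genes correlated more in the dye term (rho 0.32 over 14714 pairs) than in the pair mean (rho 0.0311). In probe order the correlation of the dye term was 0.293 at a distance of 1, 0.182 at 5 and 0.0141 at 10, against 0.0269, 0.0121 and 0.0165 for the pair mean. Genes are not independent replicates in these correlations. A single probe's gene name was thus not checked by a second probe, while the spread of some lists argues against names that are wrong throughout.

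Of the 16 sign patterns of the 5 mice, 4, the real one among them, gave 632 or more probes at an unadjusted p under 0.05 by limma. The real pattern gave 632, and the highest other gave 747. With 16 patterns a share under 0.05 cannot be reached. At an adjusted p under 0.05 each pattern gave 0 probes by limma.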
